A study of Oreochromis mossambicus with 12 samples.

How the data were processed

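RNA was profiled in head-kidney leukocytes of tilapia held in primary culture. The head kidney is the main blood-forming organ of bony fish, so its leukocyte fraction holds mature immune cells and their precursors. Per the labels, cells received PBS, heat-killed Streptococcus agalactiae at a multiplicity of infection (bacteria per cell) of 1, sodium nitrite at 1000 μM, or both agents together, and were collected after 12 h. Each of the 4 groups had 3 libraries, 12 in all. RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit, per the labels' protocols, and sequenced on an Illumina HiSeq instrument. The labels do not say whether the libraries of a group came from separate fish or cultures, so p-values measure only the spread between these libraries, which may be technical.

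The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the library's total) for 58070 transcripts, given to 2 decimals and paired with 28921 gene symbols. Trimmomatic 0.30, HISAT2 2.0.1 and HTSeq 0.6.1 were used per the submitters' processing notes. The genome build, the annotation and the tool that computed the FPKM are not given in the sources used here. Of the symbols, 18784 (64.9%) are LOC identifiers that the table does not pair with a name; 12 symbols had been turned into dates and 1 into a bare number. Gene positions were not used here.

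Transcript FPKM were summed per symbol, and 12423 genes with a mean of at least 1 FPKM over the 12 libraries were tested, 6765 of them with a symbol other than a LOC identifier. Values were transformed as log2(FPKM + 1), so fold changes are on that scale and understate the change of genes with low values. All 4 groups were fitted together with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, 8 residual degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 6 contrasts were each treatment against PBS, co-treatment against each single treatment, and the interaction. Errors of log2 changes are standard errors (SE) of the fit, and errors of FPKM are standard deviations (SD) over 3 libraries.

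The samples, tests, alternatives, 40 gene lists and the rule for named genes were fixed before the data were examined. The rule takes, per contrast, the 10 largest rises and 10 largest falls among genes past the threshold whose libraries do not overlap, with a mean of at least 5 FPKM in the higher group and a symbol other than a LOC identifier; up to 4 members of each list with the smallest adjusted p; and a fixed panel of 36 names, of which 17 were in the table and 16 were tested. The rule names more genes than the report gives. Which of them to give was decided after their values and their stability were seen, and several whose calls changed between alternatives were left out; how many of all of them kept their calls is given with the alternatives. A further gene that the rule names is not reported here for another reason than its values. Genes named outside the rule are said to have been chosen after their values were seen. Lists were matched by symbol only. Protein kinases, binding proteins, assembly factors and similar symbols that the name patterns caught by mistake were removed by name after the table had been opened. Lists with at least 3 tested members (32 of the 40) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over all 192 tests; every adjusted p of a list below comes from camera. With an estimated correlation no list was called (lowest adjusted p = 0.197).

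FPKM hold no counts, so the absolute depth is unknown. In 7746 genes with 1 transcript and many zeros, the low values stepped in a way that gave the libraries' approximate relative depth. The deepest library had about 1.43 times the depth of the shallowest, PBS replicate 1; among the other 11 libraries the ratio was 1.21. Sums of FPKM ran from 422129 in PBS replicate 1 to 503740 in nitrite replicate 3. Exact zeros in the table can be failed estimates, so a gene at 0 is described only as listed at 0. No 2 libraries held identical values.

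Replicate numbers come from the sample titles. All 18 pairs of libraries with the same number in different groups deviated together from their group means (r across genes of 0.42 to 0.92), while no pair with different numbers exceeded -0.0044, and 12 of 12 libraries correlated best with their own number. Deviations cancel within a group, so the negative r between numbers follows in part from the positive r within numbers. It is no separate evidence. The numbers were therefore taken to pair the libraries. The fit without the block is the main one, as fixed; the fit with the replicate number as a block is given where it changes the call of a list or named gene, or moves a count of genes by more than 1.5 times (within a list, also by at least 2 genes).

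Alternatives were other pseudocounts (0.1 and 3), no filter or a minimum mean of 5 FPKM, median-ratio scaling, quantile normalization, no trend, the replicate block, a minimum absolute log2 change of 1, sample weights, only the 2 groups compared in the fit, and each library left out. The fits that left out each library had no block, so they ignored the pairing. Chosen after seeing the data were transcript rows in place of gene sums, genes above 0 in all 12 libraries, and the block without PBS replicate 1. The workflow was tested on simulated data for nitrite against PBS over 12423 genes. The data were drawn from the blocked fit, with errors independent between genes and no treatment effect besides the planted changes. Recovery in the real data may therefore differ. Without the block it recovered 33% of 100 genes changed by 1 on the log2 scale and 81% of 100 changed by 2, with 0 other genes called; with the block it recovered 72% and 91%, with 8 others called. Figures were drawn with matplotlib 3.10.9.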

Results

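Transcript abundance was measured by RNA sequencing in tilapia head-kidney leukocytes after 12 h with PBS, heat-killed S. agalactiae (called bacteria here), sodium nitrite, or both (co-treatment), with 3 libraries per group. Most libraries were closest to the library of the same replicate number in the group that differed only in nitrite, as PBS replicate 2 was to nitrite replicate 2 (r = 0.992 across genes, which are not independent replicates). The exception was nitrite replicate 1, closest to PBS replicate 2 (r = 0.959). PBS replicate 1 stood apart. Its r with the other PBS libraries was 0.81 and 0.85, and ribosomal protein genes made up 4.98% of its FPKM sum against 17.6% and 16.4% in PBS replicates 2 and 3.

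**Figure D1:**
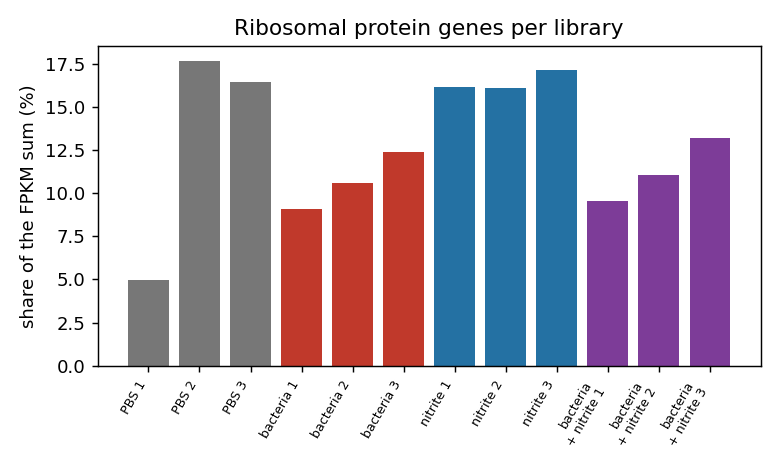
Share of the FPKM sum (%, vertical axis) taken by 67 ribosomal protein genes in each of the 12 libraries (bars, coloured by group). PBS replicate 1 lies at 4.98%, the other PBS and the nitrite libraries between 16.1% and 17.6%, and the 6 libraries with bacteria between 9.08% and 13.2%.

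The first comparison asked how leukocytes responded to the bacteria alone. acod1, the enzyme that makes itaconate in activated macrophages, rose from 0.747 ± 0.623 to 918 ± 219 FPKM (SD, n = 3 each), a log2 change of 9.07 ± 0.37 (SE). The neutrophil chemokine il-8 rose from 9.77 ± 8.32 to 2705 ± 960 FPKM (log2 8.28 ± 0.67), and il12b, a cytokine subunit, by 4.81 ± 0.26. The eosinophil peroxidase gene epx fell from 5953 ± 1090 to 126 ± 42.0 FPKM (log2 -5.58 ± 0.38), and csf1r, the receptor for a macrophage growth factor, from 49.6 ± 26.6 to 2.37 ± 1.16 FPKM (log2 -3.79 ± 0.64). In limma's test 4594 of 12423 genes passed, 1330 higher and 3264 lower, and the adjusted p was 1.34e-07 for acod1, 1.25e-05 for il-8, 4.42e-06 for epx and 0.00133 for csf1r.

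The other largest rises were in slco2a1, a prostaglandin transporter (7.64), tp53i3 (7.14), crispld2 (6.71), draxin (5.97), suox, the sulfite oxidase gene (5.84), kctd12 (5.75), lacc1 (5.44) and ptx3, a soluble pattern-recognition protein (5.15), all log2 changes. The other largest falls were in lrrc19 (-5.25), tinagl1 (-4.64), entpd1, an ectoenzyme that hydrolyses extracellular ATP (-4.50), granzyme, a protease of cytotoxic granules (-4.26), the integrin gene itga6 (-3.86), apoa4 (-3.84), lipoprotein lipase lpl (-3.80) and rtn1 (-3.71).

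**Figure D2:**
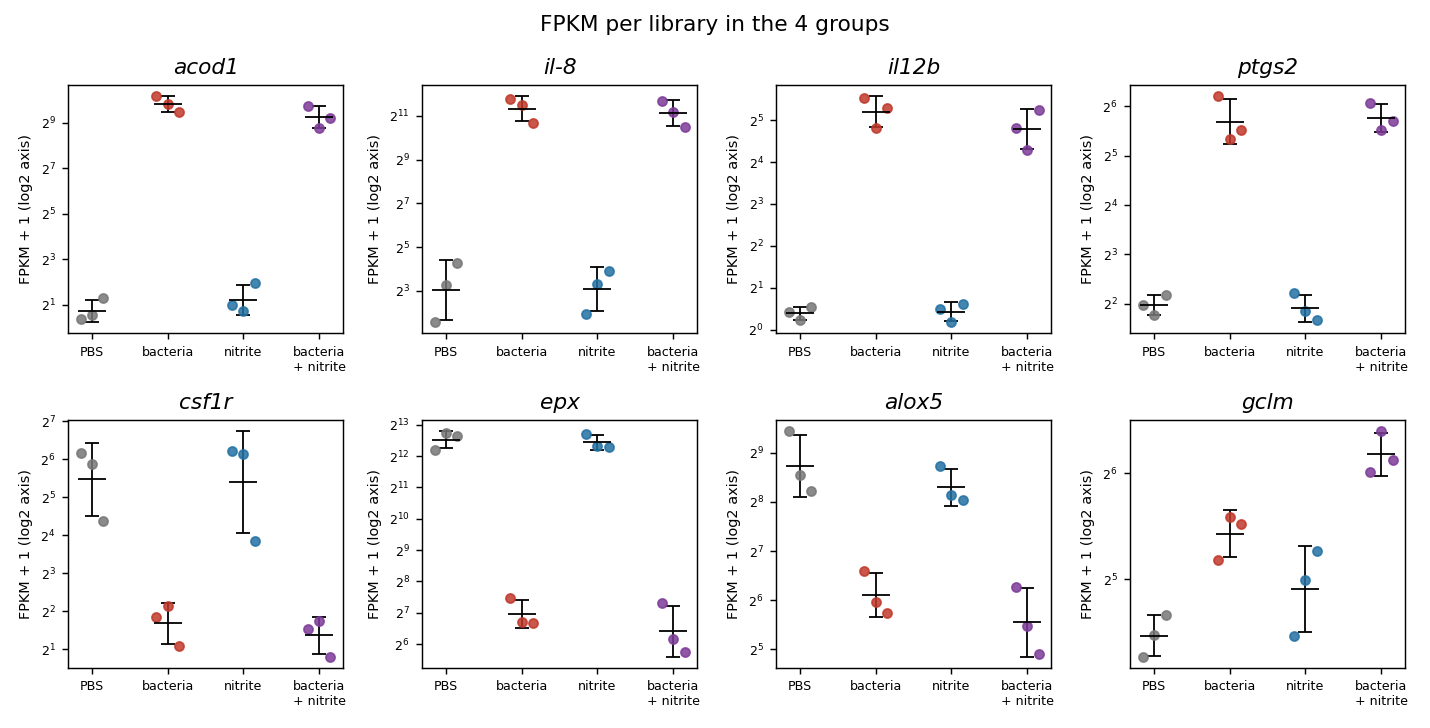
FPKM + 1 (log2 axis) of 8 genes in the 4 groups; points are libraries, horizontal bars the mean of 3 log2 values and whiskers 1 SD. acod1, il-8, il12b and ptgs2 were higher and csf1r, epx and alox5 lower in all 6 libraries with bacteria than in the 6 without, and gclm averaged 21.3 FPKM with PBS and 72.0 FPKM with co-treatment.

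Genes that restrain inflammation rose as a group with the bacteria: 7 of 10 members rose (also 7 adjusted over the list alone) and the median log2 change was 2.53, among them tnfaip3 (3.34 ± 0.21) and tnip2 (3.44 ± 0.25), both inhibitors of NF-kB signalling. NF-kB and AP-1 transcription factors had 9 of 16 rising (9 adjusted over the list alone), such as jund (3.52 ± 0.20), batf (1.93 ± 0.18) and bcl3 (1.98 ± 0.24). Among pattern-recognition receptors and their adaptors 6 of 12 rose and 1 fell (the same counts adjusted over the list alone), with card9 at 2.47 ± 0.30, ripk2 at 2.17 ± 0.21 and irak1 at 2.05 ± 0.16. The adjusted p of these lists was 3.65e-07, 1.25e-06 and 0.000128, and with an estimated correlation the adjusted p was 0.197 for each. The lists of proinflammatory cytokines and chemokines had only 2 and 1 tested genes, too few for camera. Whether such genes rose as a group was therefore not tested. Of the 2 cytokine genes 1 rose and 1 fell, and 0 fell after median-ratio scaling.

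Of 9 interferon response genes 4 rose (4 adjusted over the list alone), with irf7 at 1.36 ± 0.28 and ifi35 at 1.41 ± 0.21 on the log2 scale; the list's adjusted p was 0.00176, and the adjusted p with an estimated correlation was 0.735. Of 5 antigen presentation genes 3 rose (3 adjusted over the list alone, where 1 also fell), including the dendritic cell marker cd83 (3.80 ± 0.21) and the peptide transporter tap1 (1.38 ± 0.27); the adjusted p was 0.0234, adjusted p = 0.511 with an estimated correlation, and adjusted p = 0.0615 without PBS replicate 3. Lysosome and phagosome genes had 12 of 25 rising and 2 falling (12 and 4 adjusted over the list alone), among them the proton pump subunits atp6v1a (2.68 ± 0.23) and atp6v1h (1.64 ± 0.20). Its adjusted p was 0.000756, the adjusted p with an estimated correlation 0.480, and the call was lost after quantile normalization (adjusted p = 0.0561).

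Of 18 apoptosis and p53 genes 6 rose and 2 fell (the same adjusted over the list alone), with gadd45b at 3.48 ± 0.28, casp9, an initiator caspase, at 1.97 ± 0.26 and the survival gene bcl2l1 at 1.25 ± 0.17; the adjusted p was 0.00107, and adjusted p = 0.197 with an estimated correlation. After median-ratio scaling 11 apoptosis and p53 genes rose and 0 fell. In the list of nitric oxide and arginine metabolism 2 of 5 rose (2 adjusted over the list alone), suox and arginase arg2 (4.10 ± 0.52). Its adjusted p was 0.0213, the adjusted p with an estimated correlation 0.480 and the adjusted p with the replicate block 0.0538. Of 13 hypoxia and glycolysis genes 5 rose and 2 fell (6 and 3 adjusted over the list alone), including the glycolytic regulator pfkfb3 (4.24 ± 0.83), adm (3.28 ± 0.49) and vegfa (1.71 ± 0.24). That call (adjusted p = 0.0355, and adjusted p = 0.785 with an estimated correlation) was lost with the block (adjusted p = 0.0583), after quantile normalization (adjusted p = 0.211) and without bacteria replicate 1 (adjusted p = 0.102). All 29 proteasome genes had positive changes (median 0.78) and 6 passed, 0 adjusted over the list alone; the adjusted p was 3.66e-06, the adjusted p with an estimated correlation 0.928, and 0 members passed without PBS replicate 1. The number of proteasome genes that rose was 21 after median-ratio scaling, 19 with the replicate block and 0 after quantile normalization.

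Other lists were not called by camera but had members that passed. In the eicosanoid list 2 of 6 genes rose and 3 fell. The cyclooxygenase gene ptgs2 was among the rises (3.72 ± 0.25), while the prostaglandin E synthase ptges (-1.96 ± 0.26) and the leukotriene genes alox5 (-2.64 ± 0.41) and alox5ap (-2.29 ± 0.37) fell. Of 24 antioxidant genes 2 rose and 8 fell (3 and 10 adjusted over the list alone). gclm, a subunit of the enzyme that limits glutathione synthesis, rose by 0.96 ± 0.22, and hmox1 (-1.72 ± 0.38), sod1 (-1.45 ± 0.32), sod2 (-1.57 ± 0.29), gstk1 (-1.75 ± 0.23) and prdx5 (-1.28 ± 0.17) fell. After median-ratio scaling 5 antioxidant genes rose and 6 fell, and with the replicate block 6 rose and 12 fell. Of 11 heat shock genes 1 rose and 5 fell (1 and 6 adjusted over the list alone), and after median-ratio scaling 1 rose and 1 fell, while 3 fell without PBS replicate 1. The metalloreductase steap4 rose by 4.88 ± 0.38, the matrix protease mmp2 was -3.03 ± 0.25 and the stress gene ddit4 was -2.54 ± 0.40, both past the threshold. Of the 16 panel genes 7 rose and 4 fell, among them nfkbia (2.63 ± 0.54) and myd88 (1.74 ± 0.24). il10 (0.65 ± 0.29), gclc (0.59 ± 0.28) and bax (0.39 ± 0.18) did not pass, but did with the replicate block (adjusted p = 0.0308, 0.0154 and 0.0385) and after median-ratio scaling (adjusted p = 0.0377, 0.0106 and 0.00397), and il10 also passed without bacteria replicate 1 (adjusted p = 0.00832). bcl2 (-0.22 ± 0.17) and hsp70 (0.10 ± 0.21) passed in neither the main nor the blocked fit. They did with sample weights, whose estimation stopped before it converged (adjusted p = 0.00760 and 0.0244).

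In the fit without the block, the calls of a pair of these genes were lost when single libraries were left out, with changes of the same sign. The flagellin receptor gene tlr5 was -2.76 ± 0.78 (adjusted p = 0.0176, and 7.05e-06 with the block). It was -2.05 without PBS replicate 1 (adjusted p = 0.0559), -2.35 without bacteria replicate 3 (adjusted p = 0.0631) and -2.37 after median-ratio scaling (adjusted p = 0.0501). The sulfiredoxin gene srxn1 was -0.70 ± 0.20 (adjusted p = 0.0192, and 0.0117 with the block). It was -0.64 without PBS replicate 2 (adjusted p = 0.0614), -0.64 and -0.67 without bacteria replicates 1 and 2 (adjusted p = 0.0695 and 0.0614), -0.42 after median-ratio scaling (adjusted p = 0.134) and -0.29 after quantile normalization (adjusted p = 0.363).

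Cell type markers moved with the bacteria too. Of 6 macrophage markers 4 fell (4 adjusted over the list alone), csf1r among them. 3 of 6 progenitor markers fell (5 adjusted over the list alone), with cebpa at -2.08 ± 0.26, myb at -1.39 ± 0.18 and hmga2 at -1.61 ± 0.27. Of 6 B cell markers btk (-2.13 ± 0.22) and swap70 (-2.55 ± 0.32) fell, 4 of 6 thrombocyte markers and 2 of 5 erythroid markers fell, all 3 fibroblast markers fell (pdgfrb -2.44 ± 0.24, tagln -1.60 ± 0.35), and of 4 endothelial markers flt1 rose (4.95 ± 0.59) and 3 fell, stab1 (-2.55 ± 0.60) among them. After median-ratio scaling 2 of the macrophage and 1 of the thrombocyte markers fell, and 1 thrombocyte and 1 erythroid marker rose. Without PBS replicate 1, 2 thrombocyte markers fell and 1 rose. After quantile normalization 2 thrombocyte markers and 1 endothelial marker fell. Of 6 T cell and 4 interrenal markers 0 passed in limma's test, with 0 adjusted over the list alone, and of 5 neutrophil markers 1 rose and 1 fell. With the replicate block, and also after median-ratio scaling, 3 neutrophil markers rose, and with the block 5 progenitor markers fell. No marker list was called in this comparison (lowest adjusted p = 0.0642, progenitors).

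The balance of higher and lower genes depended on scaling. Over all tested genes the median log2 change with bacteria was -0.29 as deposited, 0.04 after median-ratio scaling and -0.05 after quantile normalization, and 29.0%, 57.6% and 48.0% of the called genes were higher, respectively. Ribosomal protein genes had a median of 0.16 in this comparison, with 0 rising and 5 of 67 falling (0 after median-ratio scaling); without PBS replicate 1 the median was -0.71 and 61 fell, and the list was called higher without PBS replicate 2 (median 0.68) or 3 (median 0.60). The median of 46 oxidative phosphorylation genes was -0.25, 0.14 after median-ratio scaling and -0.73 without PBS replicate 1, and that of 26 cell cycle genes -0.29, 0.07 and -1.02.

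The second comparison asked what nitrite did alone. il-8 was at 8.71 ± 5.61 FPKM with nitrite and 9.77 ± 8.32 with PBS (log2 0.02 ± 0.67), acod1 at 1.54 ± 1.24 and 0.747 ± 0.623, and hmox1 at 994 ± 193 and 770 ± 61.4 (log2 0.35 ± 0.38). gclm (0.44 ± 0.22) and gclc (0.49 ± 0.28), the subunits of glutamate-cysteine ligase, did not pass (adjusted p = 1 each). Limma called 0 of 12423 genes, with and without the replicate block. An unadjusted p under 0.05 was found for 74 genes, where chance gives 621, and for 489 with the block. The fit without the block counts shared differences between replicate numbers as spread, which makes its test strict. The fit with the block removes them and still stayed under chance, so they do not account for the whole shortfall. What else contributed was not tested. The 0 calls therefore do not show that nitrite had no effect.

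Ribosomal protein genes (64 of 67 positive, median 0.85, adjusted p = 1.06e-16), oxidative phosphorylation genes (40 of 46 positive, median 0.39, adjusted p = 1.49e-06) and proteasome genes (26 of 29 positive, median 0.31, adjusted p = 0.000128) were higher as lists with nitrite, with 0 members passing. The adjusted p-values with an estimated correlation were 0.823, 0.928 and 0.963. These calls moved with PBS replicate 1: without it the medians were -0.04, -0.08 and 0.01, and the adjusted p-values 0.536, 0.386 and 0.623. Without nitrite replicate 3 the adjusted p was 0.0513 for oxidative phosphorylation and 0.835 for the proteasome. The NF-kB and AP-1 list (median 0.12, adjusted p = 0.0473, adjusted p = 0.785 with an estimated correlation) was not called with the block (adjusted p = 0.0538). It was also not called without PBS replicate 1 (adjusted p = 0.252) or 2 (0.126), nitrite replicate 2 (0.0568) or 3 (0.418), or co-treatment replicate 3 (0.0512).

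Co-treatment was also set against PBS, with the same PBS libraries as in the first comparison: acod1 was 8.50 ± 0.37 higher on the log2 scale, il-8 8.07 ± 0.67 and il12b 4.39 ± 0.26, while epx fell by 6.12 ± 0.38 and csf1r by 4.11 ± 0.64. Among the 10 largest rises were fabp7 (5.16 ± 0.93), a fatty acid binding protein gene, and abtb2 (4.99 ± 0.48). Limma called 4848 genes, 1411 higher and 3437 lower (29.1% higher; 56.0% after median-ratio scaling and 47.7% after quantile normalization). gclm rose by 1.71 ± 0.22 (adjusted p = 0.000242) and gclc by 1.31 ± 0.28 (adjusted p = 0.00411), and casp9 by 1.80 ± 0.26. Of 24 antioxidant genes 4 rose and 7 fell, and after median-ratio scaling 6 rose and 5 fell. Among the falls was hmox1 (-1.32 ± 0.38, adjusted p = 0.0184), which did not pass after median-ratio scaling (adjusted p = 0.103). The camera test called 9 lists, all higher, and 0 of them with an estimated correlation (lowest adjusted p = 0.197). Besides the lists given next they were pattern recognition, NF-kB and AP-1 factors, interferon response, antigen presentation, lysosome and phagosome, apoptosis and p53, and nitric oxide and arginine. Antigen presentation (adjusted p = 0.0372) was not called without PBS replicate 3 (adjusted p = 0.0804). Of 10 genes that restrain inflammation 8 rose (8 adjusted over the list alone; median 2.30, adjusted p = 3.65e-07, adjusted p = 0.197 with an estimated correlation), and 13 of 29 proteasome genes (16 adjusted over the list alone; median 1.00, adjusted p = 2.89e-07, adjusted p = 0.851 with an estimated correlation). The number of proteasome genes that rose was 26 after median-ratio scaling, 22 with the replicate block, 8 without PBS replicate 1 and 1 after quantile normalization.

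Of the cell type markers in co-treatment against PBS, 5 of 6 progenitor (5 adjusted over the list alone), 3 of 6 thrombocyte (5), 2 of 6 macrophage (4), all 3 fibroblast (3) and 3 of 4 endothelial (3) markers fell. After median-ratio scaling 3 progenitor, 0 thrombocyte, 1 macrophage, 2 fibroblast and 2 endothelial markers fell, and after quantile normalization 3, 0, 3, 3 and 1 did. Without PBS replicate 1, 3 progenitor and 1 thrombocyte marker fell, and with the replicate block 5 thrombocyte and 4 macrophage markers did. No marker list was called in this comparison (progenitors, adjusted p = 0.0501).

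Co-treatment against nitrite asked what the bacteria did when nitrite was present. il-8 rose by 8.05 ± 0.67 on the log2 scale, acod1 by 8.01 ± 0.37, fabp7 by 5.30 ± 0.93 and ptgs2 by 3.86 ± 0.25, and epx (-6.03 ± 0.38), apoa4 (-4.43 ± 0.64), csf1r (-4.03 ± 0.64) and granzyme (-4.01 ± 0.64) fell. gclm rose by 1.27 ± 0.22 (adjusted p = 0.00159) and hmox1 fell by 1.67 ± 0.38 (adjusted p = 0.00688). In limma's test 4206 genes passed, 1314 higher and 2892 lower, and with the replicate block 6329, 1829 higher and 4500 lower; 31.2% of the called genes were higher, 57.8% after median-ratio scaling and 52.7% after quantile normalization. Of the 6 progenitor markers 5 fell (5 adjusted over the list alone), cebpa (-1.63 ± 0.26) among them; this list was called lower (adjusted p = 0.0442, adjusted p = 0.749 with an estimated correlation) but not with the block (adjusted p = 0.0730) or without PBS replicate 1 (adjusted p = 0.0960), nitrite replicate 2 (0.0534) or co-treatment replicate 3 (0.0512). The camera test called 9 other lists, all higher, and 0 of them with an estimated correlation (lowest adjusted p = 0.197). Of these, nitric oxide and arginine metabolism (adjusted p = 0.0257) was not called with the block (adjusted p = 0.0835), and antigen presentation (adjusted p = 0.0405) was not called without PBS replicate 1 (adjusted p = 0.0557) or nitrite replicate 3 (adjusted p = 0.0917).

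Other cell type markers fell in co-treatment against nitrite as well, in lists that were not called (lowest adjusted p = 0.0822, fibroblasts). They were 4 of 6 macrophage (4 adjusted over the list alone), 4 of 6 thrombocyte (4), all 3 fibroblast (3) and 3 of 4 endothelial (3) markers, and 1 thrombocyte marker rose. After median-ratio scaling 1 macrophage, 2 thrombocyte, 3 fibroblast and 2 endothelial markers fell, and after quantile normalization 4, 2, 3 and 1 did. Of the progenitor markers 4 and 3 fell after these scalings.

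The response to the bacteria was similar with and without nitrite. Over 12423 genes, which are not independent replicates, the log2 changes of the 2 comparisons correlated at r = 0.93 with a slope of 0.91. These comparisons share no library, but the same 3 replicate numbers run through both, so they are not independent. Of the 4594 genes called without nitrite, 4591 (99.9%) had the same sign with it; 1113 genes were higher in both (140.7 for independent lists) and 2488 lower in both (760 for independent lists). The interaction test called 1 gene, LOC100692258, and 50 genes had an unadjusted p under 0.05 (192 with the replicate block), where chance gives 621. It named none of il-8, acod1, gclm or hmox1 (adjusted p = 1.00 each). Counts under chance mark a strict test, and its errors were large (il-8 -0.23 ± 0.95). Few calls therefore do not show that the responses were equal.

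**Figure D3:**
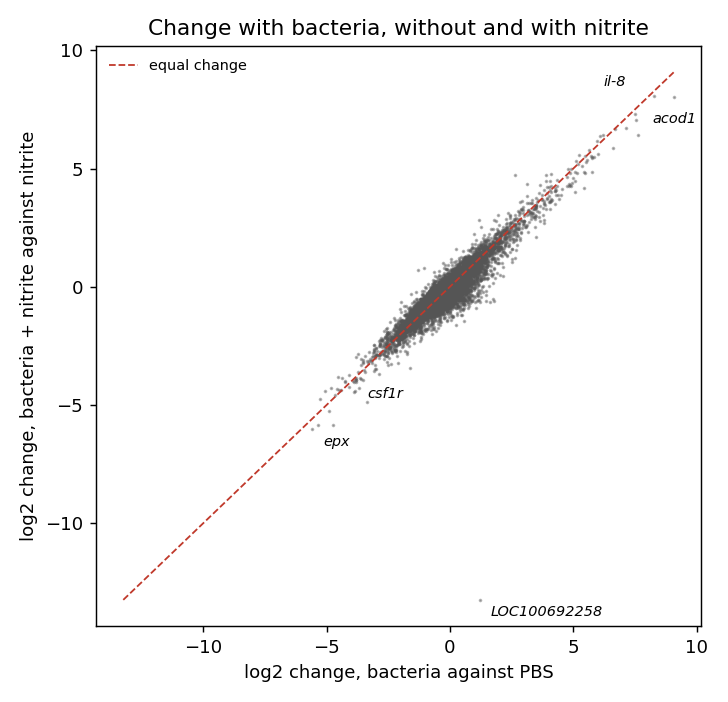
Log2 change with bacteria without nitrite (horizontal axis) and with nitrite (vertical axis) for 12423 genes (points); the dashed line marks equal change. Points lie along the line (r = 0.93), and the farthest from it is LOC100692258, which was listed at 0 in the 3 co-treated libraries.

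Co-treatment against bacteria alone asked whether nitrite changed the stimulated cells. gclm averaged 72.0 ± 10.4 FPKM with co-treatment and 42.5 ± 6.36 with bacteria (log2 0.75 ± 0.22), gclc 62.4 ± 21.2 and 36.3 ± 3.57 (0.72 ± 0.28), and the cystine transporter slc7a11 43.5 ± 10.1 and 30.4 ± 0.971 (0.48 ± 0.21), none of them past the threshold. With sample weights, whose estimation stopped before it converged, gclm and gclc passed (adjusted p = 0.0253 and 0.0260). il12b (-0.42 ± 0.26), acod1 (-0.57 ± 0.37) and il-8 (-0.21 ± 0.67) did not pass either. The antioxidant list was higher as a group (14 of 24 positive, median 0.20, adjusted p = 0.00242), and so was the proteasome list (28 of 29 positive, median 0.19, adjusted p = 0.00116), with 0 members passing in each, also adjusted over the list alone. With an estimated correlation the adjusted p was 0.574 and 0.963. The antioxidant call was lost without bacteria replicate 1 (adjusted p = 0.120) or co-treatment replicate 2 (adjusted p = 0.0759), and the proteasome call without bacteria replicate 1 (adjusted p = 0.114) or co-treatment replicate 3 (adjusted p = 0.0561).

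Limma called 1 gene in this comparison, LOC100692258, chosen for mention after its values were seen, with 156 genes at an unadjusted p under 0.05 (118 higher, 38 lower) and 432 with the replicate block, where chance gives 621. It was listed at 17476, 20799 and 18950 FPKM in the bacteria libraries, 9527, 7295 and 8120 with PBS, 10335, 9187 and 9558 with nitrite, and at 0 in all 3 co-treated libraries. The log2 changes with nitrite in this comparison and in nitrite against PBS correlated weakly across 12423 genes, at r = 0.137. This r was 0.0334 without nitrite replicate 3, 0.0381 without bacteria replicate 1, 0.0601 and 0.0790 without co-treatment replicates 3 and 2, and 0.0674 and 0.0885 without PBS replicates 1 and 2. It rose to 0.188 without nitrite replicate 1 and 0.187 without co-treatment replicate 1, and was 0.127 to 0.151 without any other library. With the replicate block 4 genes were called, the 3 others higher. Among them were LOC109202005 (1.66) and LOC100692265 (1.46), both also chosen for mention after their values were seen. As in nitrite against PBS, counts under chance mark a strict test, so few calls do not show that nitrite had no effect.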

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

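Apart from the splits of the libraries (but not the draws within replicate numbers) and the removal of single antioxidant genes, the tests below were chosen after the results were seen. A test of the difference between the responses to the bacteria with and without nitrite called LOC100692258 (log2 -14.44, which depends on the pseudocount because the co-treated libraries list 0), the oxidative phosphorylation list (median -0.29, adjusted p = 0.00161) and the ribosomal protein list (median -0.79, adjusted p = 2.04e-09). With an estimated correlation the adjusted p of the lists was 0.963 and 0.928. Without PBS replicate 1 their medians were 0.13 and 0.10 (adjusted p = 0.0222 and 0.00764), the opposite sign. With the replicate block as well, both medians were negative but far smaller, as given with the alternatives below. The size of both differences therefore rests on that library, and their reversal on a fit that ignores the pairing. The oxidative phosphorylation list was also not called without bacteria replicate 3 (adjusted p = 0.0690), nitrite replicate 3 (adjusted p = 0.426) or co-treatment replicate 1 (adjusted p = 0.0938).

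PBS replicate 1 listed ribosomal protein genes far below the other PBS libraries (median log2 difference -2.68). A feature of the cells numbered 1 as the whole cause is argued against by nitrite replicate 1, where the same genes differed by -0.0941 from nitrite replicates 2 and 3; bacteria and co-treatment replicate 1 were lower too, by smaller differences (-0.38 and -0.39), so a small part stays open. A lower depth or a factor on the whole library is argued against by 580 other genes of at least 100 FPKM, whose median difference was -0.105. Failed estimates of whole genes are argued against by the 0 of 67 ribosomal genes listed at 0. That count used sums over transcripts, so it cannot exclude failed estimates of single transcripts. Over all tested genes, PBS replicate 1 listed 95 at 0 and the other libraries 39 to 55. RNA quality, library preparation and a real difference in that culture were not tested and stay open.

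LOC100692258 was listed at 0 in all 3 co-treated libraries. A candidate explanation is an estimate that failed because the transcript was too abundant: it ranked first among all transcripts in 6 of the 9 libraries that list it, and never below rank 2, but those 9 libraries gave a value. Repression that needs both treatments is the biological alternative, with bacteria alone at 2.29 times and nitrite alone at 1.17 times the PBS level. These cannot be told apart without the reads.

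Camera called the antioxidant list higher in co-treated than in bacteria-only libraries (median log2 0.20, 14 of 24 genes positive, 0 of them past the threshold), but not with an estimated correlation (adjusted p = 0.574). A single member gene as the carrier is argued against by the list's p of at most 0.00401 after any 1 of 24 genes was removed. A p of 0.000862 (median 0.19) after quantile normalization decides nothing about scaling, since the median of all genes hardly moved (-0.0088 and -0.0093). Whether nitrite raised the list alike without bacteria stays open: the mean paired difference from PBS was 0.124 (SD 0.0367, 3 numbers), or 0.105 (SD 0.0220) without number 1 because of PBS replicate 1, against 0.194 (SD 0.0673) with bacteria, while the unpaired one without PBS replicate 1, computed first, was 0.04, and the block without that library called the list in nitrite against PBS (adjusted p = 0.00514, median 0.04). An effect of nitrite on these genes may exist, but it stays a hypothesis. The list was not called without bacteria replicate 1 (adjusted p = 0.120) or co-treatment replicate 2 (adjusted p = 0.0759). Those fits had no block and left the library of the same number unpaired, so the lost calls cannot decide whether the effect exists.

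Other splits of the 6 libraries of a comparison were fitted for each count of genes. The 10 splits are too few for a share under 0.05. Counts were 4594 for bacteria against PBS, 4848 for co-treatment against PBS, 4206 for co-treatment against nitrite and 1 for co-treatment against bacteria; in each only 1 split, the real one, gave as many, and the highest other gave 0. Every other split mixes both treatments in each group, so real differences enter the spread and lower its count by construction. In co-treatment against bacteria it also parts the libraries that list LOC100692258 at 0. The 0 calls of the other splits therefore say little about chance. For nitrite against PBS all 10 splits gave at least the real count of 0, and the highest other gave 17, from 1 of the 6 splits that part 1 replicate pair; the other 5 of these gave 0, as did the 3 other splits that part all 3 pairs. For the interaction 6 of 100 draws gave at least the real count of 1, the highest other 7; these draws ignore the replicate numbers. With the treatments permuted within each number, 5 of 100 draws gave as many, with and without the block, and the highest other gave 1. Any such draw that keeps the 3 co-treated libraries under 1 label keeps the contrast of their listed 0 with the other libraries. Some draws do so whatever the data, so the draws within numbers could not exclude chance for the count of 1. That count is not a test of LOC100692258 itself (adjusted p = 2.27e-10 in limma's test).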

How the results depend on the processing

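Chosen after the data were seen were the transcript rows, the genes above 0 in all 12 libraries, and the block without PBS replicate 1. The rule for named genes gave 380 results past the threshold, of which 255 kept their direction and their side of the threshold under every alternative run on them, with 0 reversed. Of these results 273 were not followed individually, in part because their calls were seen to change, and 155 of those 273 kept. Of the rule's 393 results not past the threshold 318 kept throughout, and 4 values under alternatives passed with the opposite sign. The 145 gene results that were followed are therefore a favourable selection: 126 kept throughout, and over all alternatives 3387 values were unchanged, 44 weaker, 32 stronger and 0 reversed. Of the 192 list tests 56 were followed, those called and all tests of 4 lists chosen after their values were seen (ribosomal, oxidative phosphorylation, antioxidant and cell cycle). Over their alternatives 1198 values were unchanged, 97 weaker, 27 stronger and 22 reversed, where reversed refers to the direction against all other genes that camera reports, which can differ from the sign of the median. Except where the construction shows it, the cause was not tested.

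Leaving out each library gave 3102 to 4931 genes for bacteria against PBS, 3676 to 5227 for co-treatment against PBS, 2907 to 5787 for co-treatment against nitrite, 0 for nitrite against PBS, 1 for co-treatment against bacteria and 1 for the interaction, 36 to 45 called lists, and r of 0.875 to 0.952 for the effect of bacteria and 0.0334 to 0.188 for that of nitrite. Leaving out PBS replicate 1 gave the highest of these counts for bacteria against PBS, co-treatment against PBS and co-treatment against nitrite. It belongs to neither group of the last comparison, so there it acted only through the spread shared by the 4 groups. A minimum log2 change of 1 left 2659, 2837 and 2437 genes in the comparisons with bacteria in that order. Sample weights, whose estimation stopped before it converged, gave 8227, 7614 and 7580, and 118 for co-treatment against bacteria, with r of 0.956 and 0.195. The replicate block gave 6329 for co-treatment against nitrite and 4 for co-treatment against bacteria; without PBS replicate 1 as well it gave 7331, 7470, 8459 and 12, with r of 0.968 and 0.283. Co-treatment against bacteria had 5 genes with no filter. With only genes above 0 in all libraries, which removes LOC100692258, it had 0 and the interaction 0 (limma; 156 and 50 at an unadjusted p under 0.05 over all genes without the block). An estimated inter-gene correlation left 0 lists.

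With sample weights, ribosomal proteins had medians of -0.69 in bacteria against PBS, -0.0701 in nitrite against PBS, -0.62 in co-treatment against PBS and 0.12 in the interaction. Over the libraries left out these ran from -0.71 to 0.68, -0.0361 to 1.35, -0.64 to 0.74 and -1.27 to 0.0976. With the block and without PBS replicate 1 they were -0.60 in bacteria against PBS, -0.54 in co-treatment against PBS and -0.00590 in the interaction. Oxidative phosphorylation genes had 0.00881 in nitrite against PBS and 0.0343 in the interaction with weights. Leaving out libraries gave -0.0793 to 0.74 and -0.66 to 0.125 there, and -0.63 to 0.15 in co-treatment against PBS. The block without PBS replicate 1 gave -0.49 in co-treatment against PBS and -0.00551 in the interaction. Cell cycle genes in nitrite against PBS had -0.25 with weights, -0.33 to 0.46 over libraries left out, and -0.11 with the block without PBS replicate 1; in the interaction leaving out libraries gave -0.44 to 0.25. Among the libraries left out, PBS replicate 1 was the only one whose omission reversed any of these lists. The relative depths are approximate, so what depth limits could not be given as counts.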

Other observations

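All values here were chosen after the data were seen. 15 genes were listed at 1 FPKM or more in all 4 libraries of a single replicate number and at 0 in the other 8: 8 for number 1, 5 for number 2 and 2 for number 3. The only one without a LOC identifier was snap25. Of the 216 ways to number the libraries, 1, the real one, gave as many, and the highest other gave 8.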
